A study of Mus musculus with 2 samples.

How the data were processed

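Total RNA from 46C mouse embryonic stem cells was labelled with Cy3 and hybridised to one-colour Agilent arrays, 1 array for shCtrl and 1 for shLincU, per the labels. The scanner files hold intensity values per spot that the authors obtained with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. Per the file headers, the processed intensity was background-corrected by spatial detrending and corrected for a multiplicative trend, an error model with a preset multiplicative error gave each spot's error, and both arrays lay on the same slide. The mean spot intensity and the median local background intensity are uncorrected, per the file headers. The deposited files also hold other columns, flags of 0 or 1 for spots well above background, positive and significant, saturated, or outliers. The deposited value table of the whole series holds log2 values with the same quantiles on both arrays and a median of 5.65 in each column, and its normalization is not given in the sources used here. Set against the scanner values over 56572 matched probes, its slope on their log2 was 1.00 for both arrays, so its scale is log2 and its direction is that of the signal; how it was centred stays unknown. Groups were taken from the genotype given in the labels. The title of the shCtrl sample calls it WT (wild type) and names no hairpin.

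The main value was log2 of the processed intensity minus the 75th percentile over non-control probes of the same array. Control spots and spots marked as non-uniform or population outliers were left out, 98 on the shCtrl array and 138 on the shLincU array. Spots of a probe were averaged; 300 probes were spotted 10 times, and the median SD between their spots was 0.038 and 0.039 log2 on the arrays. A gene's difference was the mean over its probes well above background on both arrays. In 357 genes the probes differed by more than 1. A gene with all probes below that level on one array was given a lower bound against the lowest signal well above background there, or the probe's own signal where higher. Of the 308 negative control spots, 4 were well above background on the shCtrl array and 8 on the shLincU array.

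Probes were named through a RefSeq gene table of the mouse assembly GRCm38, used for names only. By accession 32994 probes matched, 10224 by symbol and 520 by synonym, and 12867 kept the array's own name. The coordinates of long noncoding RNAs are those of the array, in build mm9.

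With 1 array per group there was no test between groups and no p-value. Genes were counted by a fixed size of 2-fold. The median of each of 27 gene lists was placed among 10000 random lists matched on 20 bins of signal level. Genes were named by a rule set before the data were examined: the 12 highest and 12 lowest with a symbol at or above the median level, up to 4 members per list with the largest difference, 5 per direction with the widest bound, 16 fixed genes of pluripotency and signalling, and the 3 highest and 3 lowest long noncoding RNAs. Other list members and gene families named in the text were chosen after their values were seen.

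The calculation was tested on simulated data at the levels and errors of the 21018 genes. Of 50 genes simulated at each size, 2 were at or above 2-fold when the true change was 1.5-fold, 21 at 2-fold, 50 at 3-fold and 50 at 4-fold. Among 20798 unchanged genes 6 passed 2-fold, under the error of the scanner software, which is mostly preset and not measured here. A simulated list of 20 genes shifted by 0.5 stood at percentile 100, and 1 of 100 unchanged lists lay outside the central 95%.

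A spot was called discordant when it differed at least 2-fold between the arrays, with signals below background raised to the lowest signal well above it. A spot was called beside discordant spots when at least 2 of its 14 nearest neighbours, within 2 rows and 1 column, were discordant in the same direction. The 384 rows were also split at the middle into upper and lower rows.

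Alternatives set before the data were examined were normexp background correction with an offset of 50 on the mean and background intensities, quantile normalization, cyclic loess, centring on the median, scaling to 7 E1A spike-in controls, the deposited value table, no background filter, genes at or above the median level, the brightest probe of a gene, outlier spots kept, other sizes (1.5-fold, 3-fold, or 2-fold beyond 1.96 times the error), another detection flag, and the mean of a list. Added after seeing the data were the upper rows, the lower rows, leaving out spots beside discordant spots, and the median over probes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.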

Results

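Gene expression was measured in mouse embryonic stem cells of the line 46C, grown with serum and LIF on feeder cells that were removed before harvest. One-colour microarrays were hybridised with RNA from 2 groups, a control short hairpin (shCtrl) and a hairpin against the long noncoding RNA LincU (shLincU), with 1 array per group. By its title the study asks whether LincU keeps cells in the naive state of pluripotency by restraining ERK signalling. The comparison is therefore between 2 arrays, it has no replicate check, and the number of arrays limits its precision. LincU itself was not analysed here, because no probe could be matched to it by name and its sequence was not used here. The knockdown was thus not checked, and every direction rests on the labels of the arrays. The control's title calls it WT, so that it carried a control hairpin rests on its genotype label alone. All differences are log2 values, shLincU minus shCtrl, and "higher" or "lower" refers to the array labelled shLincU.

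Of 56605 probes, 60.9% were well above background on the shCtrl array and 57.9% on the shLincU array. The 75th percentile of the signal was 626 and 420 intensity units, and no spot was saturated. Across the 31898 probes measured on both arrays, Pearson's r was 0.990 and Spearman's rho was 0.985; probes are not independent replicates. The median error that the scanner software assigns to a gene's difference was 0.20, which mostly reflects a multiplicative error preset in the software and is not a measured spread. Among 7144 genes with several probes, the median SD between probes of a gene was 0.18. Of 21018 genes measured on both arrays, 86.6% differed by no more than 0.5.

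Genes of the naive-to-primed transition, of gastrulation and of the early embryo differed between the arrays. Fgf8 and Fgf5, growth factors of the post-implantation epiblast and the gastrulating embryo, were higher by 2.0 and 1.41, while the core pluripotency factors Pou5f1 and Sox2 differed by -0.025 and 0.00032. The primitive streak genes Evx1 and T were higher by 1.16 and 1.1. Stra8, a gene of meiotic entry, was lower by the widest margin of any named gene, with a difference of -4.39, and Zscan4c and Zscan4f, genes of the two-cell embryo, were at -2.17 and -2.09. Of the genes in this paragraph, only Zscan4c was measured by more than 1 probe. Fgf5, Evx1 and Zscan4c lay below the median signal level of all genes. The spot of Stra8 lay in the lower rows of the array, though not beside discordant spots. In all, 240 genes were at least 2-fold higher and 322 at least 2-fold lower. Scaled to the E1A spike-in controls, which moved the median of all genes by -0.90, the split was 43 against 6914, so directions are given relative to the bulk of genes on each array.

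**Figure D1:**
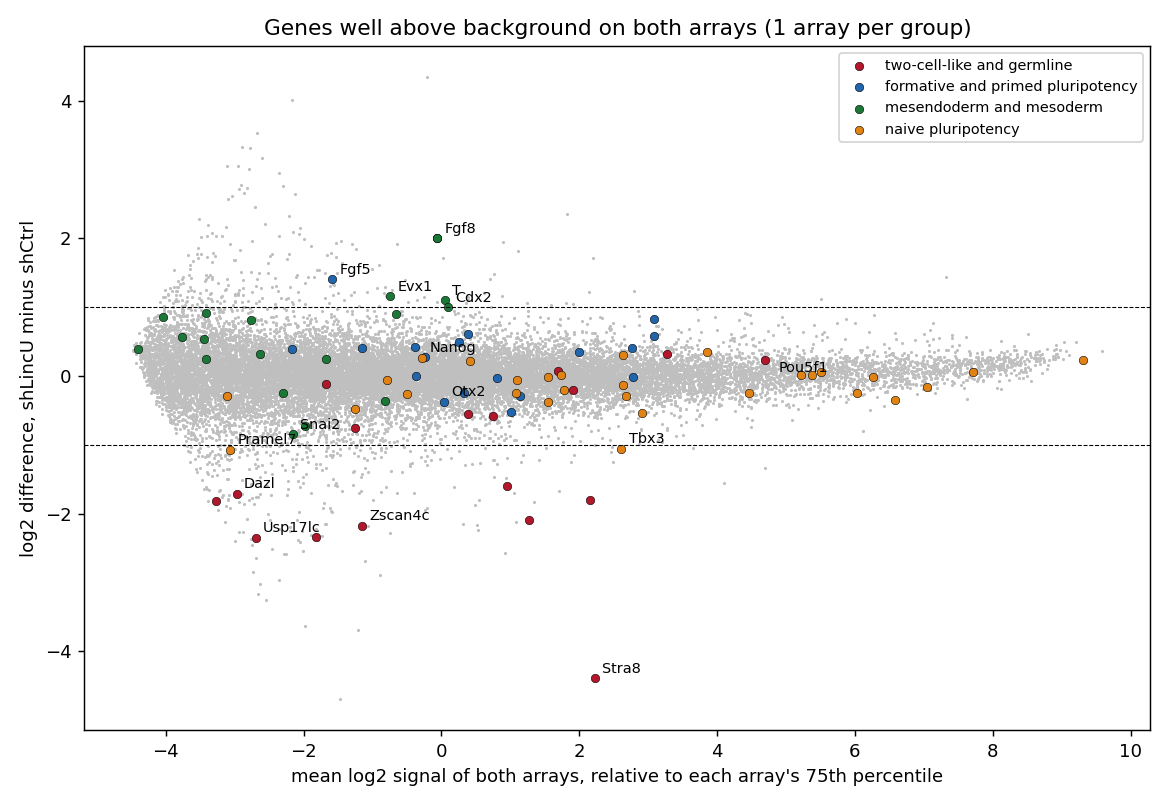
Each point is a gene measured on both arrays, with its mean log2 signal relative to each array's 75th percentile on the horizontal axis and its log2 difference (shLincU minus shCtrl) on the vertical axis; dashed lines mark 2-fold and colours mark members of 4 gene lists. Stra8 lies at -4.39 and Fgf8 at 2.0, while Pou5f1 lies at -0.025.

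The 27 gene lists were chosen before the data were examined. For each, the median difference was set among those of 10000 random lists of the same size matched on signal level, which describes these 2 arrays only. The median lay outside the central 95% of random lists for 13 lists, 9 above and 4 below, where lists of genes drawn at random would give 1.35. Genes of a list can move together between any 2 cultures, and some lists share genes such as Fgf8. The 1.35 is therefore not what chance between cultures would give. The lower rows of the array slide carried more spots that differed between the arrays than the upper rows, so each list was also read in the spots of the upper and lower rows separately. Of the 13 lists, 3 stayed outside in both parts: formative and primed pluripotency, mesendoderm and mesoderm, and two-cell-like and germline genes. Each part holds fewer members of a list, so a median inside the range there does not show that a list is unshifted. In all other settings in which they could be read, 7 of the 13 lists stayed outside. The mesendoderm and Hox lists had too few members at or above the median level to be read there. Scaling to E1A and median centring move all genes alike and test nothing here. The naive, trophoblast and stress response lists came inside among genes at or above the median level, the NODAL-activin, trophoblast and interferon lists with normexp background correction, the DUSP and interferon lists without a background filter, and the interferon list with the brightest probe.

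Naive pluripotency genes had a median of -0.13 (percentile 0.05), with 19 of 29 measured members lower. Tbx3, a transcription factor of the naive network, and Pramel7 were at least 2-fold lower, at -1.06 and -1.07. Klf4 and Esrrb were at -0.24 and -0.13, Zfp42 at -0.011 and Fgf4 at 0.061. Nanog was at 0.27, but its 2 probes differed by 1.05 and the brighter one was at -0.26. Esrrb, Zfp42, Fgf4 and Sox2 lay so near 0 that their sign changed with the processing. In the upper rows alone the naive list stood at percentile 8.0. Members of the general pluripotency list went both ways, from Gdf3 at -0.44 to Lin28a at 0.41, with a median of 0.019 (percentile 46.9).

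Formative and primed pluripotency genes had a median of 0.40 (percentile 100), with 12 of 19 members higher and 2 at least 2-fold higher, Fgf8 and Fgf5. Igfbp3 was higher by 0.83, the epiblast factor Zic2 by 0.62 and the DNA methyltransferase Dnmt3b by 0.57. Otx2 and Foxd3, transcription factors of the same state, were lower, at -0.37 and -0.52. The mesendoderm and mesoderm list had a median of 0.55 (percentile 100), with 14 of 18 members higher and 3 at least 2-fold higher: Fgf8, which both lists hold, Evx1 and T. Cdx2, Lhx1 and Wnt3 were higher by 1.0, 0.92 and 0.90, and Snai2 was lower at -0.85. Without the spots that lay beside other discordant spots, the medians of these lists were 0.40 and 0.84, though no measured probe of a formative gene lay there. Relative to random lists, the mesendoderm median of 0.53 was 0.26 with normexp background correction and 0.29 in the lower rows.

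ERK immediate early and target genes had a median of 0.18 (percentile 99.8), with 19 of 29 members higher. Fosl2, a subunit of the AP-1 factor, was the only member at least 2-fold higher, at 1.1, followed by Dusp4 at 0.87 and Epha2 at 0.67. Egr1 and Spry4, 2 widely used readouts of ERK signalling, were lower, at -0.35 and -0.44. In the lower rows alone the list stood at percentile 70.1. The DUSP phosphatases, which remove phosphate from MAP kinases, had a median of 0.30 (percentile 99.96), with 8 of 12 members higher. Dusp6 was at 0.37, Dusp9 at -0.089 and Dusp3 at -0.67. In the upper rows alone the list stood at percentile 97.3. The wider FGF and MAPK pathway list went both ways, with a median of 0.061 (percentile 79.5) and Ksr1, a scaffold of the pathway, at -0.92. The 2 probes of Ksr1 differed by 1.08, and without the one beside discordant spots it was at -0.38.

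Among other signalling lists, NODAL-activin targets had a median of -0.24 (percentile 0.63). Lefty2 and Lefty1, feedback inhibitors of NODAL, were at -0.66 and -0.60, while Skil was at 0.54. In the upper rows alone the list stood at percentile 52.2. WNT targets had a median of 0.027 (percentile 60.4), though T, Sp5 and Cdx2 were higher by 1.1, 1.04 and 1.0. Among genes at or above the median level alone, the WNT list stood at percentile 99.98. BMP-SMAD targets had a median of 0.086 (percentile 82.9), with Msx1 at 0.88 and Id1 at 0.69. LIF-STAT3 targets had a median of 0.11 (percentile 89.4), with Mcl1 at -0.47 and Il6st at 0.43.

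Two-cell-like and germline genes were shifted furthest, with a median of -1.60 (percentile 0), 14 of 17 measured members lower and 9 at least 2-fold lower. These 9 were Stra8, the deubiquitinase genes Usp17lc and Usp17la at -2.35 and -2.34, Zscan4c, Zscan4f, Tmem92 at -1.81, Tcstv3 at -1.80, the germ cell gene Dazl at -1.71 and Gm4340 at -1.60. The germline genes Ddx4 and Mael were at -0.59 and -0.55, and Zfp352 was at 0.31. With normexp background correction the list median, relative to random lists, was -0.60 in place of -1.61. Probes of near-identical family members can share signal, so single members of the Zscan4 and Usp17l families are uncertain.

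**Figure D2:**
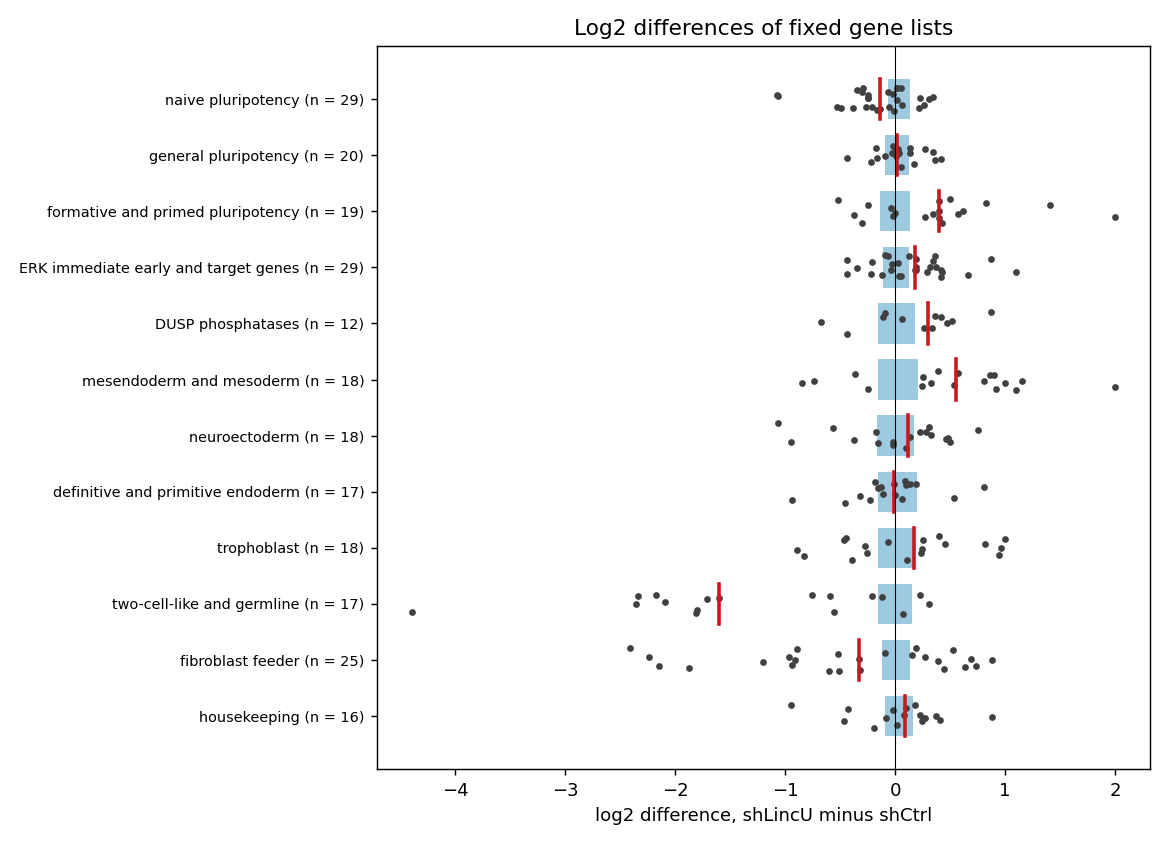
Each point is a gene's log2 difference (shLincU minus shCtrl), the red line is the median of its list, and the blue band is the central 95% of the medians of 10000 random lists matched on signal level. The two-cell-like and germline median lies at -1.60, that of mesendoderm and mesoderm at 0.55 and that of general pluripotency at 0.019.

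Lineage lists other than mesendoderm had medians nearer 0. The neuroectoderm list had a median of 0.12 (percentile 89.1), with Dll1 at -1.07, Neurod1 at -0.95 and Sox1 at 0.096, which turned negative without a background filter. The list stood at percentile 33.8 in the upper rows and 99.7 in the lower rows. The endoderm list had a median of -0.0062 (percentile 37.0), with Gata6 at 0.089 and Gata4 at 0.81. The trophoblast list had a median of 0.17 (percentile 98.2), with Peg10 and Krt8 higher by 0.96 and 0.94 and Esx1 lower at -0.89, on a single probe beside discordant spots. The trophoblast list stood at percentile 7.02 in the lower rows. Hox genes had a median of 0.38 (percentile 99.93), with 13 of 16 measured members higher. They were dim on both arrays, and Hoxc9 and Hoxd4 differed by 0.75 and 0.73. In the lower rows alone the Hox list stood at percentile 95.7.

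Markers of fibroblast feeder cells, which had been removed before harvest, had a median of -0.33 (percentile 0). Dcn, Ccl2, Lox, S100a4 and Col1a2 were at least 2-fold lower, at -2.41, -2.24, -2.15, -1.88 and -1.20. Other members were higher, among them Tagln at 0.88, Col5a1 at 0.73 and Col3a1 at 0.64. Of 5 further members seen on one array only, 2 had a bound of at least 2-fold on the shLincU array and 0 on the shCtrl array. In the lower rows alone the list stood at percentile 34.5. Epithelial-mesenchymal genes had a median of 0.28 (percentile 99.98), with the keratins Krt8, Krt18 and Krt19 higher by 0.94, 0.82 and 0.74, and stood at percentile 43.1 in the lower rows.

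Interferon response genes had a median of 0.18 (percentile 97.8), with Oasl2 at 1.07 and Ifit2 at -0.56, though Ifit2 was at 0.14 with normexp background correction. Of 4 further interferon genes seen on one array only, 2 had a bound of at least 2-fold on the shCtrl array and 0 on the shLincU array. Genes of the unfolded protein and integrated stress response had a median of 0.18 (percentile 99.6), with Chac1 at 0.68 and Xbp1 at -0.60. In the lower rows these lists stood at percentiles 78.4 and 75.2. The medians of p53 targets (0.058, percentile 80.0), glycolysis and hypoxia (-0.026, 15.6), cholesterol synthesis (0.032, 61.9) and cell cycle genes (0.0042, 33.0) lay inside the range, and so did those of imprinted genes (0.038, 68.3), ribosomal proteins (0.094, 43.6) and housekeeping genes (0.093, 81.0). Single members stood apart in both directions. Lower were the p53 target Ccng1 at -0.87, Idi1 of cholesterol synthesis at -0.93, the cyclin Ccnd2 at -0.91, the imprinted RNA H19 at -1.77 and Hprt at -0.95. Higher were the housekeeping gene Ipo8 at 0.88, the imprinted genes Peg10 at 0.96 and Igf2 at 0.86, and the cyclin Ccne2 at 0.62.

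Among the brighter genes outside these lists, the lowest were Gpat2, a glycerol-3-phosphate acyltransferase gene, at -2.58, Zscan4a at -2.17, Xlr4b at -2.15 and Zscan4b at -2.12. BB287469, AF067061 and the elastase gene Cela2a followed at -1.92, -1.80 and -1.70. Highest were Pkdcc, a secreted kinase gene, at 1.95, the mitochondrial gene ND6 at 1.82, the 28S ribosomal RNA Rn28s1 at 1.44 and Olfr1466 at 1.40. Mid1ip1, Gbp2 and Zfp703 were higher by 1.21, 1.14 and 1.1. Kcnd1 (4.35), Hmga1 (1.23), Mtfp1 (1.15) and Myh14 (1.1) owe their place to 1 probe each that lay beside other discordant spots. Without such spots Mtfp1 was at -0.25 and Myh14 at -0.15, and Hmga1 and Kcnd1 fell below 2-fold. With normexp background correction the differences of T, Evx1, Fosl2, Sp5, Pramel7, Dll1, Oasl2 and H19 kept their sign but fell below 2-fold.

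Of long noncoding RNAs at or above the median level of all genes, Dgkeos was the lowest at -1.29. It was followed by reverse-strand and forward-strand transcripts at 33923944 to 34003394 on chromosome 14 (-1.25) and 13468953 to 13474394 on chromosome 16 (-1.18), in mm9 coordinates as the array gives them. The latter fell below 2-fold with normexp background correction. The highest were transcripts at 60531602 to 60543635 on chromosome 2 (1.72), 39984031 to 40081556 on chromosome 16 (1.71) and 87483814 to 87493039 on chromosome 17 (1.16). These 3 each had a probe beside other discordant spots. Without such spots the transcript on chromosome 2 fell below 2-fold, as it did with the brightest probe, and the other transcripts had no probe left.

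Some genes were well above background on one array only and have lower bounds. There were 1677 such genes on the shCtrl array and 569 on the shLincU array, and the bound was at least 2-fold for 266 and 265 of them. Relative to the 75th percentile, the lowest log2 signal well above background was -4.72 on the shCtrl array and -4.34 on the shLincU array. Dim genes were thus harder to detect on the shLincU array, and the excess of 1677 over 569 was not separated from this. Among genes with a symbol, the widest bounds were at least 14.5-fold for Cacna2d3 and 13.2-fold for Ldc1 on the shCtrl array, and at least 22.7-fold for Nek10 and 15.5-fold for Neurl3 on the shLincU array. A transcript without a symbol had a bound of 15122-fold on the shLincU array, but its spot lay in a cluster of discordant spots of the same direction in the lower rows. Of the 10 genes with a symbol and the widest bounds, 5 per array, Ly6k alone had its spot in the upper rows.

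The position of a spot on the slide mattered for these counts. In the lower rows 4.09% of spots differed at least 2-fold between the arrays, against 1.34% in the upper rows, and 415 against 42 spots differed at least 4-fold. Of all such 2-fold spots, 54.8% had a neighbour that differed in the same direction, against at most 19.3% in 100 shuffles of the spots. With the upper rows alone, 12807 genes were measured on both arrays, against 21018 with all rows. Of the 12807, 88 were at least 2-fold higher and 150 lower, so the smaller counts partly reflect fewer genes. In the same rows 51 and 38 genes had a bound of at least 2-fold on the shCtrl and shLincU array.

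**Figure D3:**
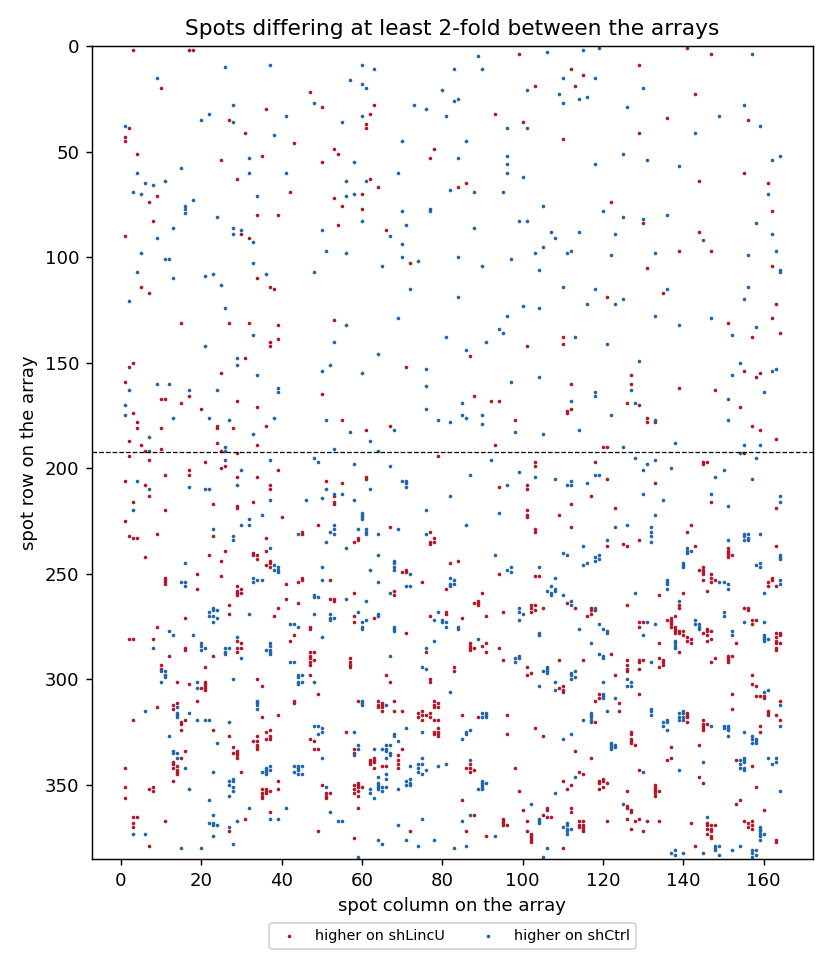
Each point is a spot whose signal differed at least 2-fold between the arrays, placed by its row and column on the slide, with signals below background set to the lowest signal well above it; red is higher on the shLincU array, blue on the shCtrl array, and the dashed line parts the upper from the lower rows. Such spots are 4.09% of those in the lower rows and 1.34% in the upper rows, and many lie in small clusters.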

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

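The upper rows, the lower rows, the removal of spots beside discordant spots and the median over probes were chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Of the 45 named genes at least 2-fold apart, all 45 stayed so with quantile normalization, cyclic loess, the deposited value table and outlier spots kept. Median centring and E1A scaling move all genes alike, so they cannot test calls made relative to the median of all genes. With normexp 33 did, without a background filter 37 and with the brightest probe 41. Without spots beside discordant spots 38 of the 43 still measured did. Of these 45 genes, the sign turned only for Myh14 (-0.16 with the brightest probe, -0.15 without such spots) and Mtfp1 (-0.25 and -0.25), because the probe that was higher was left out. Smaller differences also turned: Nanog (-0.26), Pgk1, Lss, Esrrb and Zfp42 with the brightest probe, Ifit2 (0.14) with normexp, Dnmt3l, Dusp14, Cdkn1a, Fgf4 and Sox1 without a background filter, Rps14 with quantile normalization and the deposited value table, and Sox2, near 0, in several settings. The counts of 240 higher and 322 lower genes became 95 and 108 with normexp, 43 and 6914 with E1A scaling, 1463 and 1330 without a background filter, 88 and 150 in the upper rows, and 29 and 58 at or above the median level. At 1.5-fold they were 1005 and 1017, and at 3-fold 72 and 109. Genes measured were 21018 in the main setting, 36992 without a filter, 12807 in the upper rows and 10509 at or above the median level. E1A scaling moved the median of all genes by -0.90 and dropping the filter moved it by 0.12. The lower rows gave 209 and 216. The cause was not tested. Of genes seen on one array only, the 266 on shCtrl and 265 on shLincU became 546 and 608 with the other detection flag, 58 and 142 with normexp, 51 and 38 in the upper rows, and 114 and 127 without spots beside discordant spots. List medians relative to random lists moved as follows, and beyond the pull of the normexp offset on dim genes the cause was not tested. Mesendoderm went from 0.53 to 0.26 with normexp, 0.85 in the upper rows, 0.29 in the lower rows and 0.82 without such spots. The two-cell-like list went from -1.61 to -0.60 with normexp and -0.58 at or above the median level. In the lower rows the ERK list went from 0.17 to 0.041 and the feeder list from -0.34 to -0.033. The sign turned for NODAL-activin targets in the upper rows (0.0054) and for trophoblast (-0.17) and epithelial-mesenchymal genes (-0.016) in the lower rows. Of the 2-fold genes, 29 and 58 lay at or above the median level, and dim signal was not separated from position on the slide as a limit on the counts.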

Other observations

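Gene families below were chosen after their values were seen. All tests here, those that removed spots beside discordant spots included, were chosen after the result was seen, except that of polyadenylated histone variants. All 4 measured Zscan4 genes, of which the fixed list holds Zscan4c and Zscan4f, were at least 2-fold lower, with a median of -2.15. Of 3 Usp17l genes, Usp17ld stood apart at -0.30, and of 4 Fthl17 genes 2 were at least 2-fold lower while the highest was at 0.044. The X-linked genes Xlr3b and Xlr4b were at -2.29 and -2.15. Of 7 measured Pramel genes 3 were at least 2-fold lower, and Obox6, of an oocyte homeobox family, was at -1.22. Of 15 Rhox genes, a homeobox cluster on the X chromosome, 3 were at least 2-fold lower and 1 higher. The 25 measured genes of the major histocompatibility complex, which present antigens, had a median of -0.48, with H2-Ab1 at -1.49, H2-Eb1 at -0.93 and H2-K1 at -0.48. B2m, the partner of H2-K1 but not of H2-Ab1 or H2-Eb1, was at -0.46. The fibroblast feeder list was lower too, so a different share of remaining feeder cells was not excluded for the 25 genes. Near-identical members of these families can share probe signal.

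Another group went the other way. Of 46 replication-dependent histone genes 39 were higher, with a median of 0.40 (percentile 100), among them H4c3 at 0.85 and H1f3 at 0.85. The 28S ribosomal RNA Rn28s1 was higher by 1.44 and the mitochondrial ND6 by 1.82, while the 11 mitochondrial messengers, with a median of 0.18 (percentile 93.6), lay inside the range of random lists.

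These RNAs have in common that they lack long poly(A) tails, from which labelling of this kind usually starts. A candidate explanation is a difference in RNA or priming between the samples that let more of them be labelled relative to other RNAs. Scaling to E1A moved all genes by -0.90, so the histone median of 0.40 is a rise only relative to the bulk of genes. Among these, Rn28s1 and the histones prompted the test, which took RNAs by their RefSeq class. The 58 RNAs that it classes as ribosomal, small nuclear, small nucleolar, miscellaneous or other structural RNA had a median of 0.27 (percentile 100), Rn28s1 included. Without it and the miscellaneous class, a choice made after the values were seen, the median of the other 28 was 0.61, with Rnu1b1 at 0.74, Rpph1 at 0.64 and Rn7sk at 0.51. The 29 miscellaneous RNAs left out had a median of -0.062, inside the range of random lists, and 12 of them were higher. Relative to all genes the median of the 58 was 0.25, and 0.13 in the lower rows. A larger share of cells in S phase stays open, because the cell cycle list, at percentile 33.0, has 14 of 28 members higher and mixes S phase genes with inhibitors and genes of other phases. Its Mcm genes and Pcna went both ways, from Pcna at -0.23 to Mcm2 at 0.22, below the histone median of 0.40, while Ccne2 was at 0.62. A rise of all histone genes stays open as well. Single polyadenylated variants ran from -0.13 to 0.55, and their median was 0.13. That median lay below the level set beforehand for such a rise, but the upper limit of the median, 0.31, did not. That limit is the value of H2aj, which on the shCtrl array was about as bright (8.455) as the replication-dependent H2ac10 (8.464). Signal shared between histone copies was not tested. Relative to all genes the variants' median was 0.11, but -0.022 with normexp and -0.014 in the deposited value table. In these 2 settings the replication-dependent histones were at 0.33 and 0.37. RNA quality was not measured, and a biological difference in these RNAs was not tested.

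Leaving out spots beside discordant spots kept 9 two-cell-like members at least 2-fold lower and the formative and mesendoderm lists at percentile 100. None of these 9 members, and no formative gene, had a measured probe there, so the step could not change them. Their shift thus rests on other spots. The mesendoderm list did lose members and was read with the 16 left. Signal shared by near-identical copies would leave few families, and 7 of 15 had a median at least 2-fold lower. Only Zscan4 and Usp17l hold more than 1 measured member of the list, so this count mostly repeats single genes named above. It shows only that the lower members are not confined to Zscan4 and Usp17l. A smaller share of feeder cells would raise all stem cell genes alike, which is argued against for the formative genes by the general pluripotency median of 0.019 beside 0.40. With 1 array per group, the knockdown and a chance difference between cultures cannot be told apart, and a difference in RNA or priming was not tested for these genes. That loss of LincU moves cells away from the naive state stays a hypothesis, and replicate cultures would be needed to test it.

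Genes seen on one array only with a bound of at least 2-fold may in large part come from a local disturbance of the lower rows. There 84.6% of their spots lay (exact 95% interval 81.3 to 87.6) against 49.7% of all probes. These spots count among the discordant spots that marked the lower rows, so the share is no independent test of a disturbance. The interval treats spots as independent, though discordant spots lay in clusters, so it is too narrow. Over all spots seen on one array only, whatever the bound, 2130 lay in the lower rows and 1330 in the upper rows. Expression gained or lost with the knockdown would not favour some rows, so it is argued against for that excess. In the upper rows alone there were 89 such genes, and for these expression gained or lost with the knockdown stays open, because no replicate array can show the same genes.

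Stra8 responds to retinoic acid, and its difference of -4.39 could reflect a weaker response. Other retinoic acid targets had a median of -0.096 (percentile 14.8), but 6 of 13 were higher, so the test decides nothing. Cyp26a1, a direct target, was the only one at least 2-fold apart and was higher, at 1.78, opposite to a weaker response. The next largest differences, Dhrs3 at -0.88 and Rarb at -0.69, lay on the side of a weaker response. Cdx1, seen before, is among the 13, and so is Foxa1, which the fixed endoderm list also holds.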
